A study of Mus musculus with 10 samples.

How the data were processed

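RNA of sorted mouse thymic iNKT cells was measured on 10 Affymetrix arrays in 4 groups: WT stage 1 (2 arrays), WT stage 2 (3), Id3KO stage 1 (2) and Id3KO stage 2 (3). Per the labels, the mice were 6-week-old C57BL/6 animals, cells were sorted into lysis buffer, RNA was amplified in a 2-cycle labelling protocol, and the replicates were biological. The deposited values are probe set intensities on a linear scale, which the authors normalized with RMA in a version not given, and they ran from 29 to 15399 with a median of 55.1. Log2 of the intensities was taken here, although the plan had assumed values deposited as log2. The depth of an array is not a count, so no interval for counting error was computed. The groups and their numbers were copied from the labels, which do not say that replicate numbers pair the arrays.

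Probe sets were kept when their log2 intensity was above the median of the table, 5.78, on at least 2 arrays, which left 25061 of 45037. Of these 20942 belonged to 1 gene, 593 to several and 3526 to none, by a platform annotation, and 11951 genes were covered. Where 1 value per gene was needed, the probe set with the highest mean was used. Gene order came from a RefSeq gene table of the mouse reference, and positions are not printed because the sources used here name no genome build.

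limma 3.58.1 in R 4.3.3 was fitted with 1 mean per group over all 4 groups, with moderated variances (6 residual and 2.80 prior degrees of freedom) and two-sided tests. The 5 contrasts tested were Id3KO against WT at each stage, stage 2 against stage 1 in each genotype, and their interaction. P-values were adjusted by Benjamini and Hochberg over the kept probe sets of each contrast, and an adjusted p under 0.05 is a call. Group differences are log2 fold changes with the standard error of the moderated fit.

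Gene lists were fixed before the data were examined, as were the model, the filter, the alternatives, the rule for named genes and the tests unless stated. Of 27 lists, 23 had at least 5 kept genes and were tested: E and Id proteins, NKT1 and NK receptor, NKT2, NKT17, follicular helper, gamma delta T cell, double-positive thymocyte, naive and emigration, immediate early, S phase, G2 and M phase, Myc and nucleolar, glycolysis, oxidative phosphorylation, cholesterol synthesis, survival, cytokine signalling, SLAM and adhesion, type I interferon, heat shock and stress, B cell, myeloid and dendritic cell, and thymic epithelial. The sort marker, regulatory T cell and sex-linked lists had 4 kept genes each and the erythroid list 1, so they were not tested. The sex-linked genes kept were Xist, Eif2s3y, Kdm5d and Uty, and whether the groups differ in sex stays open. Shifts were tested with limma's camera at a preset correlation of 0.01, adjusted over all lists and the 5 contrasts together. Camera with an estimated correlation and fry were also run. The estimated setting raised p also for lists whose estimate lay below 0.01. A call lost under it is therefore not a measure of correlation alone. The fry p tests whether the genes of a set move on balance in one direction, and neither it nor its mixed p compares the set with other genes.

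The named genes are Id3, then for each group comparison the 10 highest and 10 lowest log2 fold changes, and for the interaction the 5 highest and 5 lowest, among called probe sets of 1 gene without overlap between the arrays of the groups. One probe set per gene was taken, the one of highest mean, and gene models named by Gm, Rik or a number were left out. Any member of a fixed list could be named as an example of its list. Eomes and the genes beside Id3 were named after their values were seen.

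The genotype effects of both stages were compared across genes by Pearson and Spearman correlation, with the error from leaving out each array in turn, and by one-sided Fisher's exact tests on the called genes. Covariance with the WT stage difference was set against 100 simulations with no effect and the same shared arrays. Calls among the 100 genes on either side of Id3 were compared with those elsewhere by one-sided Fisher's exact tests. The pipeline was tested on simulated data with independent normal noise and changes of several known sizes planted together. Of the calls, 5.56% at stage 1 and 3.45% at stage 2 were false. So were 6.62% between stages in WT, 5.30% in Id3KO and 5.56% in the interaction.

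Alternatives were no filter, a stricter filter at log2 6.50 (15259 probe sets), a further quantile normalization, arrays centred on their medians, an intensity trend with a robust prior, array weights, only the arrays compared, the replicate number as a block, 1 probe set per gene, a fold change of at least 2, the mean of all probe sets per gene for lists, 50 or 200 neighbours, and each array left out in turn. Fits averaging genotype over the stages or stage over the genotypes, and a block with the numbers of the Id3KO stage 1 arrays crossed, were added after the data were seen. The deviations of same-numbered arrays from their group means had correlations of -0.311 to 0.133, so the numbers were not treated as pairs. Those of differently numbered arrays reached 0.311. That value is the -0.311 with its sign turned, since the 2 arrays of a stage 1 group deviate from their mean in exactly opposite ways. Id3KO stage 1 replicate 2 and Id3KO stage 2 replicate 1 had a correlation of 0.989, against 0.979 between the Id3KO stage 1 arrays. A shared source under other numbers was therefore not excluded, and all arrays were fitted as independent. The planned comparison of control probe sets for RNA quality could not be made because 0 such probe sets were deposited.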

Results

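Gene expression was measured in invariant natural killer T (iNKT) cells, thymus-derived T cells with a semi-invariant receptor for lipids presented by CD1d. The cells were sorted from the thymi of 6-week-old wild-type (WT) mice and of mice that lack Id3 (Id3KO), an inhibitor of the E protein family of transcription factors. Tetramer-binding cells without CD24 and NK1.1 were divided by CD44 into stage 1, which lacks it, and stage 2, which carries it. There were 2 arrays each for WT and Id3KO at stage 1 and 3 arrays each at stage 2. The median intensity of the 10 arrays lay between 54.8 and 55.5, and their number limits the precision of every value below. Of 45037 probe sets, 25061 were bright enough to be tested, and these covered 11951 genes. The first principal component, with 33.1% of the variance, separated the genotypes. On the second, with 16.6%, the stages overlapped in Id3KO but not in WT. The WT stage 1 arrays stood at 20.4 and 8.3 there, and the WT stage 2 arrays at 7.0, -16.3 and -19.7. The Id3KO stage 1 arrays lay furthest apart of any group on it, at -20.3 and 15.5. The correlation between arrays of a group was 0.975 to 0.989, that between stages of a genotype 0.976 to 0.989, and that between genotypes 0.962 to 0.981.

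**Figure D1:**
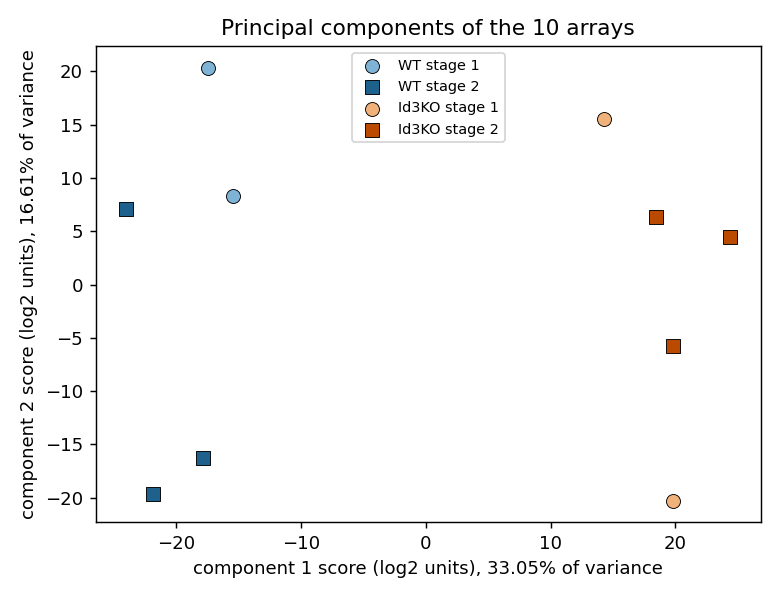
Scores of the 10 arrays on the first and second principal components of the tested probe sets, in log2 units; colours and symbols mark genotype and stage. The 5 WT arrays lie between -24.0 and -15.5 on the first component, and the 5 Id3KO arrays between 14.3 and 24.4.

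Id3, the targeted gene, was lower on all 5 Id3KO arrays than on any WT array. Its single probe set had a mean intensity of 1285 ± 4.79 (SD, n = 2) in WT stage 1 cells against 64.4 ± 1.45 (SD, n = 2) in Id3KO cells, a 19.97-fold difference (log2 fold change -4.32 ± 0.16, SE, limma adjusted p = 1.83e-05). At stage 2 the intensities were 904.7 ± 139 and 63.8 ± 8.37 (SD, n = 3 each), a 14.2-fold difference (log2 fold change -3.83 ± 0.13, SE, adjusted p = 9.02e-06). Whether the probe set lies in the deleted part of the gene is not given in the sources used here. Id3 was at -0.52 ± 0.14 (log2, SE) between stages 2 and 1 in WT cells, which did not pass the test (adjusted p = 0.385).

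At stage 1, the comparison of Id3KO with WT asks which transcripts differ without Id3 in cells that lack CD44. At either stage, arrays of sorted populations cannot tell a change within cells from a change in the mix of iNKT subsets. Gzma, which encodes the cytotoxic granule protease granzyme A, was 22.1-fold higher in Id3KO cells (log2 4.46 ± 0.36, SE, n = 2 against 2, limma adjusted p = 0.00251). Garem1, an adaptor in growth factor receptor signalling, was higher by 3.83 ± 0.31 (log2, SE, adjusted p = 0.00251). Klra8, the natural killer (NK) cell activating receptor Ly49H, was higher by 3.54 ± 0.34 (log2, SE, adjusted p = 0.00417). The WT means of Garem1 (5.34) and Klra8 (5.37) lay below the level for keeping a probe set, 5.78 on the log2 scale, so these sizes are against background and no fold is given. The probe set of Klra8 is of a class that can bind transcripts of related Klra genes, and another such probe set, assigned to Klra9 and Klra3 together, was higher by 3.36. Those of Klra7 (1.65, limma adjusted p = 0.0763) and of Klra22 and Klra1 together (0.50, 0.155) did not pass. In the other direction, Itgae, the alpha E chain of the integrin CD103 that binds E-cadherin, was 4.97-fold lower (log2 -2.31 ± 0.26, SE, adjusted p = 0.01004).

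The other largest increases at stage 1 were in Tcf24, a basic helix-loop-helix factor (2.52 on the log2 scale), Itm2a, a membrane protein of T cell development (2.45), the secreted proteins Prg4 (2.21), Fbn2 (2.01) and Stc2 (1.91), the membrane traffic gene Exph5 (1.91), and the adhesion molecule Chl1 (1.89). The largest decreases after Id3 and Itgae were in Capg, an actin-capping protein (-1.99 ± 0.13, SE, adjusted p = 0.00111), App, the amyloid precursor protein (-1.96), Smo, the transducer of Hedgehog signals (-1.82), Abca1, a cholesterol exporter (-1.74), Lgals3, galectin 3 (-1.72), Lmo4, a LIM-only cofactor (-1.72), F2r, the thrombin receptor (-1.63), and S100a4, a calcium-binding protein (-1.53). The WT means of Tcf24 (5.68) and Fbn2 (5.64) and the Id3KO mean of App (5.782 against 5.784) also lay below the level for keeping a probe set. A further probe set of App (-0.55, adjusted p = 0.115) and of Stc2 (0.21, adjusted p = 0.471) did not pass. Eomes, a T-box factor of NK and memory T cells, was singled out after its values were seen. Its brighter probe set stood at 1.33 (adjusted p = 0.0929) and did not pass, except without Id3KO replicate 1 of stage 2 (0.0482, and up to 0.430 over the other settings), and its dimmer one rose by 1.44 ± 0.18 (SE, adjusted p = 0.0118), both from WT means below that level (5.66 and 5.33).

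In all, 115 probe sets (79 genes) were higher and 86 (67 genes) lower at stage 1, and 66 and 47 of these differed at least 2-fold. The arrays of the genotypes did not overlap for 41.5% of the probe sets, against 33.3% by chance. The call of Gzma was lost when only the 4 stage 1 arrays were fitted (adjusted p = 0.0640, the highest of any setting), as was that of Klra8 (0.0719, the highest of any setting), and the counts then fell to 16 higher and 12 lower. Klra8 was also lost without WT replicate 1 of stage 1 (0.0580), and Itgae without WT replicate 1 (0.0938), WT replicate 2 (0.0713) or Id3KO replicate 2 (0.0566) of stage 1. They were 9 and 6 without WT replicate 1, 18 and 15 without WT replicate 2, 38 and 27 without Id3KO replicate 1, and 52 and 24 without Id3KO replicate 2 of stage 1. The lower count was 46 without replicate 2 and 56 without replicate 3 of WT stage 2. Of the 20 genes named above by size of change, 5 passed without each array in turn, namely Id3, Gzma, Garem1, Capg and Lmo4.

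Genes of the NKT17 program, the subset that makes interleukin 17, were lower at stage 1 as a group, with a median of -0.50 (camera adjusted p = 2.6e-07, but adjusted p = 0.332 with an estimated correlation). Rora, a nuclear receptor of that program (-1.46 ± 0.13, SE, adjusted p = 0.00303), and Maf, a transcription factor that promotes it (-1.05 ± 0.14, SE, adjusted p = 0.0158), fell, and 14 of the 16 members did not pass the test. Adjusted over the list alone, 6 members fell, and without WT replicate 1 of stage 1 the median was -0.29. Of the lists called by camera in any comparison, 0 were called with an estimated correlation. Follicular helper genes stood higher, with a median of 0.38 over 14 genes (camera adjusted p = 9.70e-07; adjusted p = 0.205 with an estimated correlation). Izumo1r, the folate receptor 4 of helper and regulatory T cells, rose (0.98), 13 members did not pass, and 5 rose when adjusted over the list alone.

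The 5 E and Id protein genes had a median of -0.42 (camera adjusted p = 0.000413; adjusted p = 0.205 with an estimated correlation), and the member that fell was Id3 itself, or 2 members when adjusted over the list alone. The list holds the targeted gene and was not tested without it, so its call at either stage says little of the other members. Without a filter the median of the E and Id list was -0.18. Type I interferon response genes had a median of -0.22 over 20 genes (camera adjusted p = 0.00255; adjusted p = 0.538 with an estimated correlation), with 0 members called by limma and 2 lower when adjusted over the list alone. Without Id3KO replicate 2 of stage 1 the camera adjusted p of the interferon list was 0.206, and without Id3KO replicate 1 its median was -0.35. Medians of 0.13 were found for the 22 Myc and nucleolar genes (camera adjusted p = 0.00595; adjusted p = 0.310 with an estimated correlation) and for the 17 cholesterol synthesis genes (camera adjusted p = 0.0218; adjusted p = 0.310 with an estimated correlation). In both of these lists 0 members were called, over all probe sets or when adjusted over the list alone. Without Id3KO replicate 1 the camera adjusted p was 0.139 for the Myc list and 0.0918 for the cholesterol list, which stood at 0.200 without WT replicate 2. Outside these lists, Cd2 (1.14), an adhesion receptor, Slamf6 (0.51), a receptor of the SLAM family, and Asns (1.84), asparagine synthetase, rose, while Il13 (-0.98), which encodes a type 2 cytokine, fell. Of the 7 list members called at stage 1 beyond the largest changes, Rora alone passed without each array in turn. Tbx21, the T-box factor T-bet, stood at -0.80 (adjusted p = 0.234), and Zbtb16, the factor PLZF that directs iNKT development, at -0.21 (adjusted p = 0.644). Neither passed.

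At stage 2 the same comparison covers cells that have acquired CD44. Gzma was again 15.4-fold higher in Id3KO cells (log2 3.95 ± 0.30, SE, n = 3 against 3, limma adjusted p = 0.000454), Garem1 was higher by 3.11 ± 0.25 and Klra8 by 2.50 ± 0.28 (log2, SE), with WT means of 5.29 and 5.55 below the level for keeping a probe set. Itgae was 14.2-fold lower (log2 -3.83 ± 0.21, SE, adjusted p = 0.000179). Ccr6, a chemokine receptor of interleukin 17 producing cells, was 10.4-fold lower (log2 -3.38 ± 0.21, SE, adjusted p = 0.000206).

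**Figure D2:**
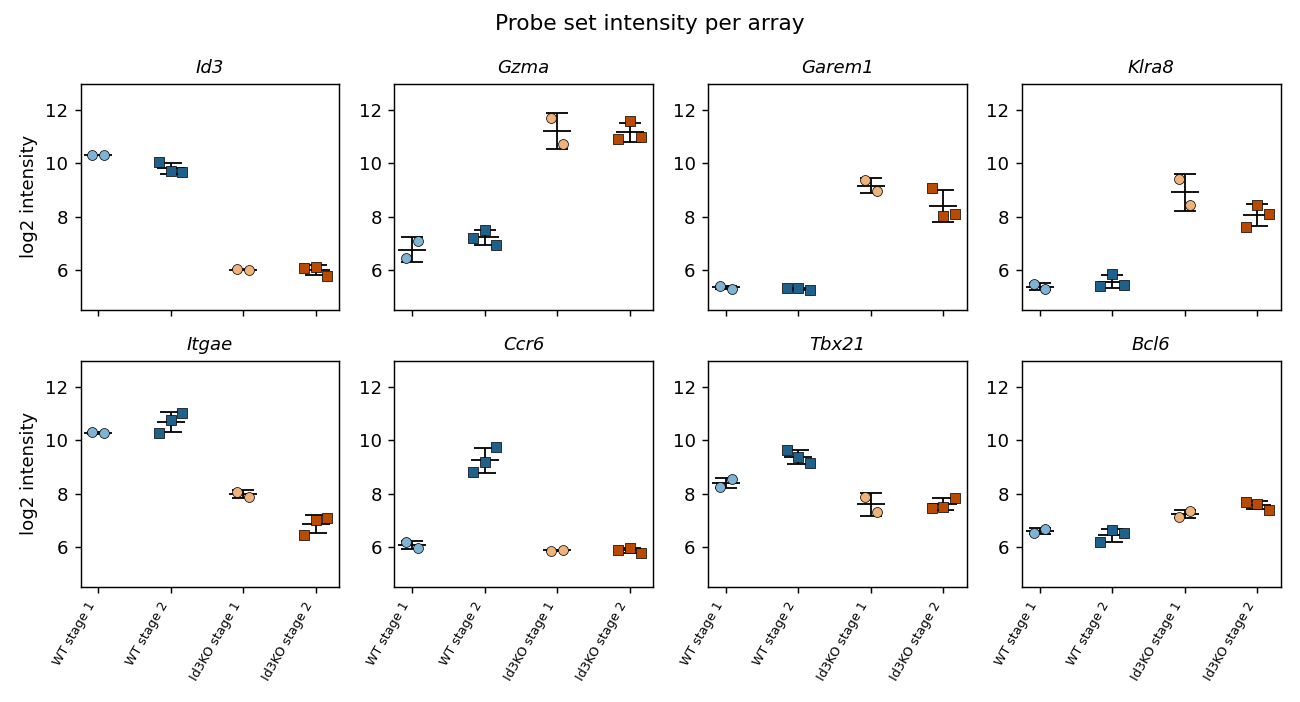
Log2 probe set intensity of 8 genes on each array; points are arrays, coloured by genotype and stage, and bars give the mean and SD of each group (n = 2 at stage 1, n = 3 at stage 2). Gzma, Garem1 and Klra8 are higher and Id3 and Itgae lower on every Id3KO array, while Ccr6 is high on the WT stage 2 arrays alone, with a mean of 9.25.

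The other largest increases at stage 2 included those of Chl1 (2.49), Asns (2.30), Homer2, a scaffold protein (2.14), Tcf24 (2.14), Prg4 (2.12) and Gsn, the actin-severing protein gelsolin (2.10). Large decreases were found for Sdc1, the proteoglycan syndecan 1 (-2.97 ± 0.35, SE), Serpinb1a, a protease inhibitor (-2.77 ± 0.33, SE), Lgals3 (-2.61), Ikzf3, the lymphoid factor Aiolos (-2.45), Ahr, the aryl hydrocarbon receptor (-2.32), Il17re, a subunit of the receptor for interleukin 17C (-2.30), and Socs3, an inhibitor of cytokine signals (-2.29). Other probe sets of Homer2 (0.01 and 1.16) and a further one of Sdc1 (0.01), of Ikzf3 (-0.43, adjusted p = 0.215) and of Il17re (-0.41, adjusted p = 0.0880) did not pass. The Id3KO means of Sdc1 (5.58) and Ahr (5.596) and the WT mean of Tcf24 (5.59) lay below the level for keeping a probe set. The dimmer probe set of Eomes rose by 0.91 ± 0.14 (SE, adjusted p = 0.00999), and its brighter one stood at 0.61 (adjusted p = 0.221).

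In all, 457 probe sets (326 genes) were higher and 598 (450 genes) lower at stage 2, with 122 and 139 of them at least 2-fold apart, and 2 genes had probe sets in both directions. The arrays of the genotypes did not overlap for 21.4% of the probe sets, against 10% by chance. All 20 genes with the largest changes passed without each array in turn and in each of the other settings tried. The counts fell to 249 higher and 332 lower without WT replicate 2, to 238 and 266 without WT replicate 3, and to 302 and 348 without Id3KO replicate 2 of stage 2, and they were 293 and 333 when only the 6 stage 2 arrays were fitted.

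NKT17 genes were lower as a group at stage 2, with a median of -1.10 (camera adjusted p = 2.80e-18; adjusted p = 0.206 with an estimated correlation). Of 16 measured members, 13 fell, 0 rose and 3 did not pass limma's test, and 15 fell when adjusted over the list alone. Besides Ccr6, Sdc1, Serpinb1a and Il17re, the falling members included Tmem176b (-2.11) and Tmem176a (-2.00), a pair of membrane proteins, Il1r1, the interleukin 1 receptor (-1.73), Rora (-1.16) and Maf (-0.88).

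NKT1 and NK receptor genes, which mark the subset that makes interferon gamma, moved in both directions. Of 29 members 12 fell, 2 rose and 15 did not pass, with a median of -0.61 (camera adjusted p = 1.39e-06; adjusted p = 0.324 with an estimated correlation). Adjusted over the list alone, 18 fell and 5 rose. Tbx21 fell by 1.79 ± 0.19 (SE, adjusted p = 0.00185), as did Cxcr3, a chemokine receptor (-1.68), Cd7, a surface receptor (-1.68), Il18rap, part of the interleukin 18 receptor (-1.58), Gzmb, granzyme B (-1.11), and Ifng, interferon gamma (-0.69). The Id3KO mean of Ifng (5.51) lay below the level for keeping a probe set. The members that rose were Gzma and Klra7, another Ly49 receptor (1.53). The call of Klra7 was lost without WT replicate 2 or 3 and without Id3KO replicate 1 or 2 of stage 2, with an adjusted p of up to 0.0660.

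Follicular helper genes were higher at stage 2, with a median of 0.55 (camera adjusted p = 3.28e-06; adjusted p = 0.205 with an estimated correlation). Of 14 members 7 rose, 0 fell and 7 did not pass, with Tox2, a nuclear factor of helper cells (1.46), Bcl6, the factor that directs follicular helper fate (1.12), Sostdc1, a secreted signalling inhibitor (1.05), and Cd200, an inhibitory ligand (0.84), as the largest. The WT mean of Sostdc1 (5.56) lay below the level for keeping a probe set. Adjusted over the list alone, 8 rose and 1 fell. Cxcr5, the receptor that guides cells to follicles, stood at 1.14 and did not pass (adjusted p = 0.0623, and 0.0138 to 0.180 over the other settings). Cxcr5 passed with the stricter filter (0.0408), array weights (0.0217) or 1 probe set per gene (0.0409), and without Id3KO replicate 3 of stage 2 (0.0138).

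**Figure D3:**
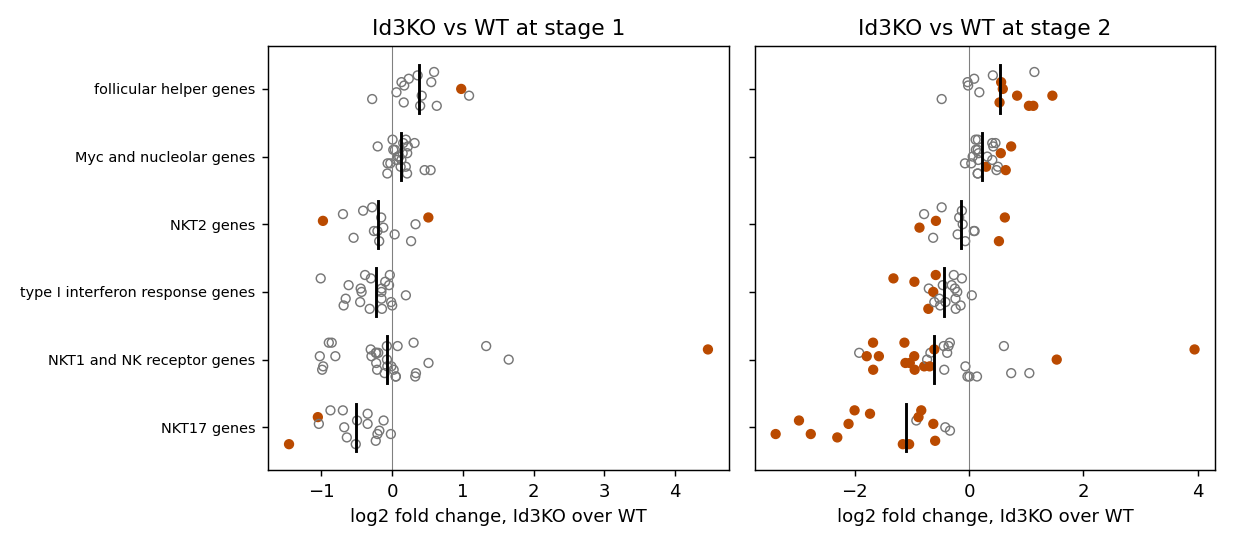
Log2 fold change of Id3KO over WT for each measured member of 6 gene lists at stage 1 and stage 2; filled points passed the test over all probe sets and vertical bars mark the medians. NKT17 genes have medians of -0.50 and -1.10 and follicular helper genes 0.38 and 0.55 at the 2 stages.

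Myc and nucleolar genes were higher as a group at stage 2, with a median of 0.23 over 22 genes (camera adjusted p = 6.21e-07; adjusted p = 0.205 with an estimated correlation). Wdr12 (0.74), Srm (0.64), Gnl3 (0.56) and Mybbp1a (0.30), which serve ribosome assembly, polyamine synthesis and nucleolar function, rose, 18 did not pass, and 10 rose when adjusted over the list alone. Heat shock and stress genes had a median of 0.25 over 19 genes (camera adjusted p = 0.00206; adjusted p = 0.310 with an estimated correlation). Asns rose and 18 did not pass, while 9 rose and 1 fell when adjusted over the list alone.

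Type I interferon response genes were lower, with a median of -0.43 over 20 genes (camera adjusted p = 1.36e-07; adjusted p = 0.310 with an estimated correlation). Ifit3 (-1.32), Mx1 (-0.95), Oasl1 (-0.71), Irf7 (-0.63) and Rtp4 (-0.58) fell, 15 did not pass, and 11 fell when adjusted over the list alone. Cytokine signalling genes had a median of -0.16 over 25 genes (camera adjusted p = 0.0122; adjusted p = 0.349 with an estimated correlation). Socs3, Il7r, the interleukin 7 receptor (-1.07), the interferon gamma receptor chains Ifngr2 (-0.76) and Ifngr1 (-0.72), and Tgfbr1, a receptor for transforming growth factor beta (-0.61), fell, 20 did not pass, and 6 fell and 2 rose when adjusted over the list alone. The camera adjusted p of the cytokine list was 0.0505 with the stricter filter on dim probe sets, 0.0648 without WT replicate 3 and 0.0581 without Id3KO replicate 1 of stage 2. The E and Id protein list had a median of -0.12 (camera adjusted p = 0.00881; adjusted p = 0.266 with an estimated correlation), with Id3 again as the member that fell, or 2 members when adjusted over the list alone. That median was -0.32 without WT replicate 2, -0.19 without Id3KO replicate 1 and -0.21 without Id3KO replicate 2 of stage 2. Id2, the related inhibitor, stood at -0.70 and did not pass (adjusted p = 0.0583, and 0.0113 to 0.185 over the other settings). It passed with the stricter filter (0.0426), with an intensity trend (0.0471), with array weights (0.0231), with the replicate number as a block (0.0129), with 1 probe set per gene (0.0382) and without Id3KO replicate 3 of stage 2 (0.0113).

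Members of lists that camera did not call or that were too short to test changed as well. Ccr9, a homing receptor of thymus and gut (1.55), and Lef1, a factor of early T cells (0.90), rose, while Itgb7, the partner chain of Itgae (-0.90), and Foxo1, a factor of naive T cells (-0.84), fell. Cd2 (1.06) and Slamf6 (0.63) rose and Icam1, an adhesion ligand (-1.07), fell. Thy1, a surface protein of T cells, fell (-1.39), as did Capg (-2.17) and Tnfrsf1b, a receptor for tumour necrosis factor (-1.03). Zbtb16 stood at 0.08 (adjusted p = 0.775). Of the 66 further list members called at stage 2, 31 passed without each array in turn; Foxo1, Il7r, Ifngr1, Tgfbr1, Irf7, Oasl1, Ifit3, Rtp4, Srm, Gnl3, Wdr12, Mybbp1a and Cd1d1 were among the others.

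The genotype differences of both stages, which share no arrays, were correlated. Across 11951 genes, which are not independent replicates, the correlation of the log2 fold changes was 0.625 ± 0.100 (jackknife SE over arrays), with a rank correlation of 0.368. Genes higher at both stages numbered 62 against 1.68 for independent lists, and genes lower at both 43 against 1.77 (one-sided Fisher's exact test, p = 6.84e-94 and 2.06e-54), and 0 genes were called in opposite directions. The calls of both stages use 1 variance per probe set, taken from all 10 arrays. The lists are therefore not independent, and the expected numbers and exact p-values are not a valid reference for the overlap. Gzma, Garem1, Klra8, Chl1 and Asns were higher, and Itgae, Lgals3, Capg, Rora and Maf lower, at both. The arrays that moved the stage 1 counts moved these too: without WT stage 1 replicate 1, 5 higher and 5 lower genes were called at both stages, without its replicate 2, 12 and 10, and without Id3KO stage 1 replicate 1, 23 and 16, without its replicate 2, 17 and 13, without WT stage 2 replicate 2, 37 and 22, and without its replicate 3, 37 and 26.

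**Figure D4:**
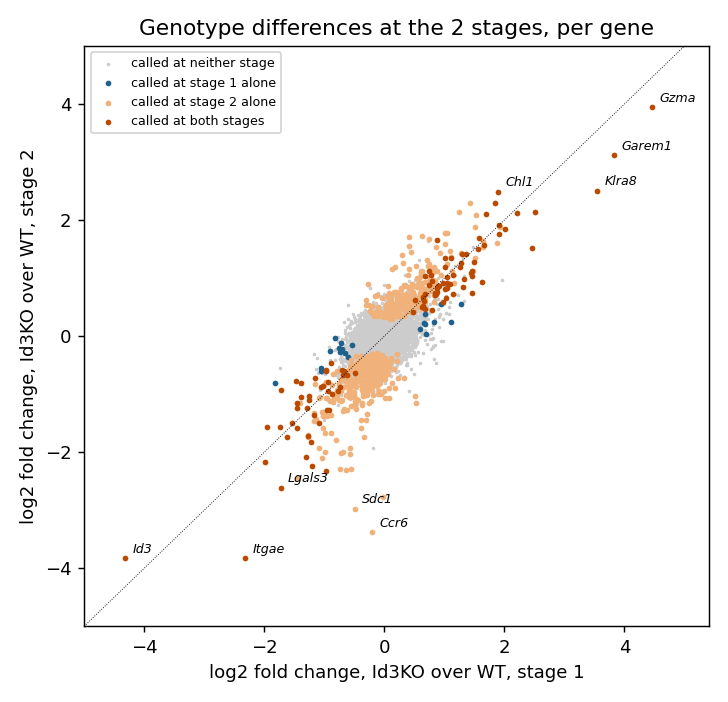
Log2 fold change of Id3KO over WT at stage 1 (horizontal) and stage 2 (vertical), 1 point per gene; colours mark the stages at which a gene was called and the dotted line marks equal change. The correlation is 0.625 and the slope of stage 2 on stage 1 is 0.713, and Ccr6 and Sdc1 lie far below the line.

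Genes beside Id3 on its chromosome were called more often than others. Among the 100 genes on either side, 4 of the 76 tested were called at stage 1, or 5.26% against 1.02% elsewhere (one-sided Fisher's exact test, p = 0.00825). At stage 2 they were 9 of 76, or 11.8% against 5.53% (same exact test, p = 0.0249). Runx3, a factor that represses Cd4 and promotes cytotoxic fate, was lower (-1.30 and -2.09), with a further probe set at -0.14 and -0.08 that did not pass. Sh3bgrl3, a small protein related to glutaredoxin (-1.18 and -1.36), and Pnrc2, a nuclear receptor cofactor (-0.69 and -0.68), were lower too, and Ubxn11 was higher (1.57 and 1.51). At stage 1 the call of Runx3 was lost without WT replicate 1 (adjusted p = 0.0938) or 2 (0.0826) of stage 1 and with only the stage 1 arrays (0.114). That of Sh3bgrl3 was lost without WT replicate 1 (0.0938) or 2 (0.0640) or Id3KO replicate 1 (0.0628) of stage 1 and with only those arrays (0.0760). That of Ubxn11 was lost with only those arrays (0.0640). Pnrc2 stood at an adjusted p of 0.0498 and passed in 7 of 20 other settings, with an adjusted p of up to 0.314. With 50 genes on either side, where 39 were tested, 5.13% and 10.3% were called at the stages (p = 0.0628 and 0.171, exact test), and with 200 genes, where 141 were tested, 3.55% and 9.22% (p = 0.0163 and 0.0510). The test around Klra8 was set after its change was seen. There, 1 of 25 neighbours was called at stage 1 (one-sided Fisher's exact test, p = 0.232) and 6 of 25 at stage 2 (p = 0.00209), namely Cd69, Klra7 and Ybx3, which were higher, and Klrb1b, Klrb1f and Klrd1, which were lower. With 50 genes on either side they were 0 of 13 and 5 of 13 (exact p = 1 and 0.000469).

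The comparison of stage 2 with stage 1 in WT cells asks what accompanies the gain of CD44. Ccr6 rose 9.07-fold (log2 3.18 ± 0.23, SE, n = 3 against 2, limma adjusted p = 0.00358), Ahr 2.65-fold (log2 1.41 ± 0.15, SE, adjusted p = 0.0484) and Clnk, an adaptor of immune receptor signalling, by 1.19 ± 0.08 (log2, SE, adjusted p = 0.00335) from a stage 1 mean of 5.17, below the level for keeping a probe set. Ccr9 fell 2.24-fold (log2 -1.16 ± 0.11, SE, adjusted p = 0.0178), with its other probe sets between -1.08 and -0.13 and not called. No other probe set passed, and 2019 had an unadjusted p under 0.05 against 1253 by chance. The arrays of the stages did not overlap for 26.2% of probe sets against 20% by chance. Without either WT stage 1 array, when only the WT arrays were fitted, or with the replicate number as a block, none of these 4 genes passed, with an adjusted p of up to 0.158 for Ccr6, 0.277 for Ahr, 0.0715 for Clnk and 0.191 for Ccr9. Ahr and Ccr9 were also lost without WT stage 2 replicate 2 (0.0502 each), its replicate 3 (0.102 and 0.0666), Id3KO stage 1 replicate 1 (0.122 and 0.0518) or its replicate 2 (0.123 and 0.0519), and Ahr without WT stage 2 replicate 1 (0.0587), Id3KO stage 2 replicate 1 (0.106), the filter (0.0938) or with arrays centred on their medians (0.0515). The counts were 9 higher and 2 lower without WT stage 2 replicate 1, and 5 and 2 without Id3KO stage 2 replicate 2.

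Cd44, whose product defined the sort, stood at 2.07 ± 0.36 (log2, SE, adjusted p = 0.134). Large values that did not pass were those of Serpinb1a (3.28, adjusted p = 0.0516), Il17re (1.85, 0.0850), Il1r1 (1.46, 0.137), Tbx21 (0.99, 0.234) and Nkg7, a granule protein (1.53, 0.510). The stage 1 mean of Serpinb1a (5.49) lay below the level for keeping a probe set. The adjusted p of Serpinb1a was 0.0147 to 0.403 over the other settings. It passed with the stricter filter (0.0238), quantile normalization (0.0495), an intensity trend (0.0284), array weights (0.0147) or 1 probe set per gene (0.0193), and without WT stage 2 replicate 1 (0.0363) or Id3KO stage 2 replicate 1 (0.0407) or 2 (0.0418). Il17re passed with array weights (0.0358) and without Id3KO stage 2 replicate 2 (0.0445), and Nkg7 when only the WT arrays were fitted (0.0349).

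NKT1 and NK receptor genes were higher at stage 2 in WT cells, with a median of 0.45 over 29 genes (camera adjusted p = 1.22e-17; adjusted p = 0.205 with an estimated correlation). Of these, 0 were called by limma over all probe sets, and 12 rose when adjusted over the list alone. NKT17 genes had a median of 0.74 over 16 genes (camera adjusted p = 1.89e-13; adjusted p = 0.306 with an estimated correlation). Ccr6 rose, 15 did not pass, and 9 rose and 2 fell when adjusted over the list alone. The 25 cytokine signalling genes had a median of 0.14 (camera adjusted p = 0.00156; adjusted p = 0.310 with an estimated correlation), with 0 members called and 3 higher when adjusted over the list alone. S phase genes were at -0.18 over 26 genes (camera adjusted p = 0.000832; adjusted p = 0.584 with an estimated correlation) and Myc and nucleolar genes at -0.14 over 22 (camera adjusted p = 0.00296; adjusted p = 0.306 with an estimated correlation), with 0 members called either way in both. Without WT stage 1 replicate 2 the camera adjusted p was 0.0857 for the S phase list and 0.0959 for the Myc list, and without WT stage 2 replicate 3 it was 0.189 for the S phase list, which stood at 0.0683 with the replicate number as a block.

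In Id3KO cells 0 probe sets passed limma's test between the stages, and 1131 had an unadjusted p under 0.05 against 1253 by chance. Cd44 stood at 1.25 ± 0.36 (log2, SE, n = 3 against 2, adjusted p = 1.00), Sox4, a factor of early lymphocytes, at -0.83 (adjusted p = 0.811) and Tbx21 at 0.01. Sox4 stood at -0.94 in WT cells (adjusted p = 0.0959), where it passed with array weights (0.0358) and without Id3KO stage 2 replicate 2 (0.0445). In data simulated with these arrays, 73.1% of changes of 1 on the log2 scale were recovered in this comparison, and 23.9% of changes of 0.5. That simulation also held 66 changes of 2, which ease the adjusted threshold for the smaller ones. A lone change of 1 in the real comparison is therefore less likely to be found. Naive and emigration genes, which include Ccr7 and Klf2, had a median of -0.34 over 17 genes (camera adjusted p = 5.71e-08; adjusted p = 0.310 with an estimated correlation), with 1 member lower when adjusted over the list alone. Without Id3KO stage 2 replicate 2 the median of the naive list was -0.14, still called by camera, and the list stood at -0.59 on that array against -0.003 and 0.083 on the other Id3KO stage 2 arrays. G2 and M phase genes were at 0.20 over 29 genes (camera adjusted p = 0.0125; adjusted p = 0.855 with an estimated correlation), with 0 members called either way. Follicular helper genes were at 0.09 over 14 genes (camera adjusted p = 0.0380; adjusted p = 0.393 with an estimated correlation) and cytokine signalling genes at -0.07 over 25 (camera adjusted p = 0.00409; adjusted p = 0.310 with an estimated correlation), with 1 member higher in the former and 2 lower in the latter when adjusted over the list alone. The G2 and M phase, follicular helper and cytokine calls were each lost without Id3KO stage 1 replicate 1 (camera adjusted p = 0.283, 0.283 and 0.0792) and without Id3KO stage 2 replicate 1 (0.283, 0.121 and 0.116), and the first of them also without its replicate 2 (0.447), as was the second (0.142). The follicular helper call was lost as well without WT stage 1 replicate 2 (0.0510) or WT stage 2 replicate 3 (0.0520). Without Id3KO stage 1 replicate 2 the medians of the G2 and M phase, follicular helper and cytokine lists were 0.33, 0.16 and -0.12, and without Id3KO stage 2 replicate 3 they were 0.45, 0.18 and -0.19.

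The interaction of genotype and stage asks whether the stage difference depends on the genotype. Ccr6 stood at -3.18 ± 0.33 and Clnk at -1.15 ± 0.11 (log2, SE, 10 arrays), that is, their rise in WT cells was absent from the Id3KO values, with an adjusted p of 0.0644 for both in limma. In all 0 probe sets passed, with 1772 under an unadjusted p of 0.05 against 1253 by chance. Over the other settings the adjusted p was 0.0170 to 0.613 for Ccr6 and 0.0222 to 0.466 for Clnk. Both passed with 1 probe set per gene (0.0222 each) and with array weights (0.0355 each), Ccr6 with the stricter filter (0.0439) and without WT stage 2 replicate 1 (0.0187) or 3 (0.0170), and Clnk without a filter (0.0319) and with an intensity trend (0.0282). Simulated differences of 1 on the log2 scale, planted beside larger ones in the same way, were recovered in 40.3% of cases.

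Over gene lists, the interaction had a median of -0.52 for the NKT1 and NK receptor genes (camera adjusted p = 1.13e-08; adjusted p = 0.310 with an estimated correlation) and -0.67 for the NKT17 genes (camera adjusted p = 1.57e-07; adjusted p = 0.326 with an estimated correlation), with 3 and 7 members lower when adjusted over the list alone. Cytokine signalling genes were at -0.24 (camera adjusted p = 3.28e-06; adjusted p = 0.206 with an estimated correlation) and SLAM and adhesion genes at -0.25 (camera adjusted p = 0.0111; adjusted p = 0.516 with an estimated correlation), with 3 and 1 members lower. Type I interferon genes were at -0.15 (camera adjusted p = 0.0209; adjusted p = 0.649 with an estimated correlation) and Myc and nucleolar genes at 0.13 (camera adjusted p = 0.0218; adjusted p = 0.310 with an estimated correlation), with 0 members called either way. The Myc call was lost when the arrays were quantile normalized again (camera adjusted p = 0.0532). It was also lost without WT stage 1 replicate 2 (0.150), Id3KO stage 1 replicate 2 (0.218) or Id3KO stage 2 replicate 1 (0.105). The SLAM call was lost without Id3KO stage 1 replicate 1 (0.0918) or Id3KO stage 2 replicate 2 (0.0939), and the SLAM median was -0.15 without WT stage 1 replicate 2 and -0.14 without Id3KO stage 1 replicate 2. The interferon call was lost without WT stage 1 replicate 1 (0.0518), WT stage 2 replicate 3 (0.189), Id3KO stage 1 replicate 1 (0.233), or Id3KO stage 2 replicate 1 (0.132) or 2 (0.108). The interferon median was -0.27 without WT stage 1 replicate 2, -0.24 without WT stage 2 replicate 1 and -0.23 without Id3KO stage 2 replicate 3.

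Along the WT stage difference, the genotype difference at stage 2 had a covariance of -0.0288, against -0.00895 simulated with no effect for arrays shared in this way, a difference of -0.0199 ± 0.00536 (jackknife SE). At stage 1 the covariance was 0.0112 against 0.0135, a difference of -0.0023 ± 0.0126 (jackknife SE) that lies within its error. The correlations read differently, at -0.457 against -0.447 simulated with no effect at stage 2, and 0.202 against 0.549 at stage 1. The stage differences of the 2 genotypes had a correlation of 0.01 across genes.

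The sort could hold other cells. Their B cell, myeloid, epithelial and double-positive lists were called by neither camera nor fry in any of the 5 comparisons. Adjusted over the list alone, 1 B cell marker was higher at stage 1, and 3 were higher and 1 lower at stage 2. Of the myeloid markers, 1 was higher and 2 lower at stage 1, and 1 was lower at stage 2, as was 1 double-positive gene. The medians lay between -0.05 and 0.07 for 8 B cell markers, between -0.03 and 0.05 for 9 myeloid and dendritic cell markers, between -0.02 and 0.06 for 8 thymic epithelial markers, and between -0.08 and -0.02 for 13 genes of immature double-positive thymocytes. Of 20 natural killer cell markers listed after the genotype differences were seen, of which 16 are also in the NKT1 list, 14 were tested, with medians of -0.15 at stage 1 and -0.71 at stage 2, and at stage 2 7 fell and 0 rose. Single members did change at stage 2, where Ighm (0.88), the heavy chain of immunoglobulin M, rose, and Ctss, cathepsin S (-0.76), and Cd1d1, which presents lipids to iNKT cells (-0.78), fell. The NKT2 list had medians between -0.19 and 0.05 over 14 genes, the gamma delta T cell list between -0.47 and 0.02 over 7, the immediate early list between -0.18 and 0.14 over 23, the survival list between -0.20 and 0.03 over 18, the glycolysis list between -0.08 and 0.11 over 12, and the oxidative phosphorylation list between -0.04 and 0.03 over 23. None of these 10 lists was called by camera in any comparison. The fry test, which does not compare a list with other genes, called the survival list lower at stage 2 (median -0.20, fry adjusted p = 0.0183, camera adjusted p = 0.0711). The median, mean and test of a list differed in sign at stage 1 for the NKT1, double-positive, naive, SLAM and B cell lists, at stage 2 for the S phase and myeloid lists, between stages in WT for the gamma delta, G2 and M phase and myeloid lists, between stages in Id3KO for the E and Id, B cell, myeloid and epithelial lists, and in the interaction for the NKT2 and myeloid lists, each of which was not called there.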

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

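The tests of CD44 separation, of single arrays and of the splits below were chosen after the result was seen. That on the array's floor was set after the pattern was seen, but before its own result. A difference between the genotypes in the stage effect, tested as the interaction of genotype and stage, marked out 6 gene lists. The median interaction was -0.5189 for the NKT1 and NK receptor genes, -0.6691 for the NKT17 genes, 0.1274 for the Myc and nucleolar genes, -0.2374 for the cytokine signalling genes, -0.252 for the SLAM and adhesion genes and -0.1532 for the type I interferon genes. None of the 6 was called with an estimated correlation, where the adjusted p was 0.310, 0.326, 0.310, 0.206, 0.516 and 0.649.

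NKT1 and NKT17 genes were higher at stage 2 than at stage 1 by a median of 0.49 in WT cells and stood at 0.01 in Id3KO cells, over 45 members of both lists. The tables argue against 1 array as the source, since the median interaction was -0.412 at its closest to 0 without 1 array, and against a rise hidden at the array's floor as the whole explanation, since it was -0.519 over the 21 members bright in both Id3KO groups (16 below 0, sign-flip permutation p = 0.0013, over genes that are not independent, while 17 of 60 splits of the arrays gave these members a median as far from 0, up to 1.25). Choosing members by brightness in Id3KO favours genes that are higher there. The member at that median was Gzma (-0.5189), which was higher in Id3KO cells at both stages. A weaker separation of the stages on CD44 in Id3KO cannot be told apart: the lists kept a share of 0.018 of their WT rise, below the share of Cd44 by more than 2 standard errors on 2 of its 3 probe sets (0.604 ± 0.205 and 0.586 ± 0.189, SE) but not on the third (0.403 ± 0.197), and the bright members kept a share of 0.254, not below it on any. Chance could not be excluded, since 11 of 60 splits of the arrays between genotypes within each stage gave a median as far from 0 as the real -0.52, with 1.04 as the largest size of the others, although splits that exchange arrays within 1 stage carry the genotype difference itself. A dependence of the NKT1 and NKT17 programs on Id3 at stage 2 stays a hypothesis. More arrays may test it, but arrays of sorted populations cannot tell it from a change in the mix of subsets.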

How the results depend on the processing

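The averaged fits and the block with crossed numbers were chosen after the result was seen, and the other alternatives before. All 20 genes with the largest changes at stage 2 passed in each setting and without each array, and at stage 1, 3 of 20 did in each setting. No list called by camera held with an estimated correlation, so lists called were 0 in all 5 comparisons (6, 8, 5, 4 and 6 in the order stage 1, stage 2, WT, Id3KO, interaction). Correlation alone does not account for these losses. The E and Id list at stage 1 had an estimate of -0.058, below the preset 0.01. Its unadjusted camera p was nevertheless 0.00611 with the estimate against 5.03e-05 with the preset. With fry the lists called were 2 at stage 1, 9 at stage 2 (the 8 called by camera and the survival list), 3 in WT, 0 in Id3KO and 0 for the interaction. The camera and fry counts at stages 1 and 2 include the E and Id list, which holds Id3. Without a filter the lists called were 10 at stage 1, 8 in Id3KO and 10 for the interaction. The interaction had 1 lower probe set without a filter, 1 with the stricter filter, 1 with an intensity trend and robust prior, 2 with array weights and 2 with 1 probe set per gene, against 0. Higher probe sets between stages in WT, 3 in all, were 6 with the stricter filter, 7 with quantile normalization again, 8 with an intensity trend, 31 with array weights (11 lower) and 7 with 1 probe set per gene. With only the arrays of the groups compared, which leaves fewer arrays for the spread, the counts were 16 higher and 12 lower at stage 1, 293 and 333 at stage 2, and 0 lower in WT. A change of at least 2-fold, which can only remove calls, left 66 higher and 47 lower at stage 1 and 122 and 139 at stage 2. Averaged over the stages, with 5 arrays against 5, the genotype comparison gave 547 higher and 698 lower probe sets. The stage comparison averaged over the genotypes gave 1 higher and 0 lower. The covariance at stage 2 with the WT stage difference, beyond that of shared arrays, was -0.01323 without a filter and -0.02655 with the stricter filter. With 50 genes on either side of Id3, where fewer genes are tested, the p-values were 0.06276 and 0.1705, and with 200 it was 0.05096 at stage 2. Tbx21 between stages in Id3KO, at 0.01 and not called, was 0 with arrays centred on their medians and -0.029 with array weights. Except where a reason is given, the cause was not tested.

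The replicate number as a block costs degrees of freedom, and no pairing by number was found. With it, 54 probe sets were higher and 45 lower at stage 1, and 0 and 0 between stages in WT. Genes called at both stages were then 31 higher and 23 lower, and 8 lists were called in Id3KO. With the numbers of the Id3KO stage 1 arrays crossed in the block, stage 1 had 93 higher and 76 lower.

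Leaving out 1 array in turn, of which a lone stage 1 array was assumed to vary like the others, gave 9 to 127 higher and 6 to 107 lower probe sets at stage 1, 238 to 408 and 266 to 491 at stage 2, 0 to 9 and 0 to 2 between stages in WT, and 0 to 1 lower for the interaction. Lists called ranged from 4 to 9 in WT, 2 to 9 in Id3KO and 4 to 11 for the interaction. Genes called at both stages were 5 to 67 higher and 5 to 52 lower. Id3 was at -4.343 to -4.297 at stage 1 and -3.895 to -3.702 at stage 2, the correlation between stages 0.5306 to 0.6299, and the covariance beyond shared arrays -0.01123 to 0.005678 at stage 1 and -0.02257 to -0.01713 at stage 2. Values near 0 that were not called turned direction: Tbx21 in Id3KO ranged from -0.289 to 0.303 and Zbtb16 at stage 2 from -0.004 to 0.143.

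Clnk, Ifng, Klrb1b, Ltb4r1 and the E and Id list had no value under the stricter filter, Klrb1b none without WT stage 2 replicate 1 or 3, and the interaction none with only the arrays compared. Changes among dim genes are limited by signal over background.

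Medians of some lists moved by more than 1.5 times. At stage 1 they ranged over the settings from -0.479 to -0.177 for the E and Id list, -0.625 to -0.2592 for NKT17 genes, 0.07709 to 0.1676 for cholesterol synthesis genes and -0.3505 to -0.1659 for interferon genes, and at stage 2 from -0.3221 to -0.1094 for the E and Id list and -0.20 to -0.1041 for cytokine genes. Between stages in WT, S phase genes ranged from -0.2394 to -0.07109. In Id3KO the ranges were 0.05114 to 0.4548 for G2 and M phase genes, 0.02198 to 0.179 for follicular helper genes, -0.1948 to -0.05492 for cytokine genes and -0.4187 to -0.1417 for naive genes. For the interaction they were -0.2865 to -0.1315 for SLAM genes, -0.2724 to -0.1006 for interferon genes and 0.07702 to 0.1741 for Myc genes.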

Other observations

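The averaged fits, the test on natural killer cells and all splits were chosen after the result was seen. The test on genes beside Id3 was chosen before. That around Klra8 was set after the change of Klra8 was seen, but before its own result. Averaged over the stages, 547 probe sets were higher and 698 lower in Id3KO cells. Of 60 splits of the arrays within each stage, 1, the real split, gave as many as 1245, with 0 as the highest of the others. These splits count against an accidental division of the arrays only if the arrays of both stages are independent, which the labels do not say. At stage 2 alone 10 splits are too few for a share under 0.05. There the real split called 1055 probe sets, and the highest other 0, so that 1 split gave as many. It called 8 lists and the highest other 12, with 3 splits that called as many. Between the stages averaged over the genotypes, 1 probe set was called, and chance was not excluded, since 11 of 100 splits gave as many, with 13 as the highest other.

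Gzma, Garem1 and Klra8 were higher in Id3KO at both stages. Natural killer cells in the Id3KO sorts, which the gate on tetramer binding without NK1.1 should remove, cannot be told apart from a change in iNKT cells. The median change of 14 markers was -0.15 at stage 1 and -0.71 at stage 2. Of the 20 markers listed, 16 are also in the NKT1 list, whose fall at stage 2 could hide a rise there. At stage 1 that list had a median of -0.07 and was not called (camera adjusted p = 0.711). Without the filter 19 markers had values, and 14 of them were dim in WT. The medians of these dim markers were -0.084 at stage 1 and -0.097 at stage 2, with Eomes (1.33) and Fcer1g (0.738) as the highest. Some markers near the floor in WT did not differ upward, such as Ncr1 (-0.076 and -0.132 at stages 1 and 2), Tyrobp (-0.096 and -0.002) and Prf1 (-0.009 and -0.062). Others stood higher, such as Klre1 (0.328 and 0.14) and, at stage 2, Fcer1g (0.738), and the dimmer probe set of Eomes was called higher at both (1.44 and 0.91). Whether DNA of another strain in the natural killer gene complex may carry the change of Klra8 cannot be told apart, since calls among its neighbours had a one-sided Fisher's exact p of 0.2317 at stage 1 and 0.00209 at stage 2 with 25 genes tested (0 of 13 and 5 of 13 within 50 genes). Of the genes called at stage 2, Klrb1b and Klrd1 fell and are in the NKT1 list, which camera called lower there. Klra7, also in that list, rose, as did Cd69 and Ybx3, while Klrb1f, which is outside it, fell. Probe sets that bind related Klra transcripts stay open as well and were not tested.

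Runx3, Sh3bgrl3, Pnrc2 and Ubxn11, which lie near Id3, were called at both stages. DNA of another strain around the targeted allele is a candidate explanation, since calls were enriched among 100 genes on either side at both stages, with 0.02494 as the larger one-sided Fisher's exact p. With 50 genes on either side the shares called were similar (5.13% and 10.3%) but over fewer genes, with a p of 0.0628 and 0.171, and at stage 1 the calls of Pnrc2, Runx3 and Sh3bgrl3 were lost without single arrays. An effect of Id3 on these genes stays open and was not tested.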
